A study of Mus musculus with 20 samples.

How the data were processed

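RNA was measured by sequencing in striatum and hippocampus of mice of the strain C57BL/6 labelled wild type or full knockout of Helios, the zinc finger transcription factor encoded by Ikzf2. There were 20 libraries in 4 groups of 5. Per the labels' protocols, libraries were made with a stranded TruSeq mRNA kit and sequenced on a NextSeq500 as single reads of 75 bp. Per the submitters' processing notes, CASAVA 1.8.2, bcl2fastq 2.15.0, FastQC 0.11, cutadapt 1.3, BWA 0.7.4, SAMtools, HTSeq, DESeq2 and featureCounts were used with the mouse build mm10. The notes as used here give neither the role nor the order of these tools. Groups and replicate numbers were taken from the library titles. The hippocampal library labelled knockout replicate 10 carried the tissue tag striatum, while its title and description said hippocampus, and it was placed in hippocampus.

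The authors deposited a table of RPKM, reads scaled to gene length and library size, for 27179 genes and 20 libraries. The authors also deposited 1 table per tissue of their own comparison, with log2 fold changes, standard errors on the log2 scale, p-values and adjusted p-values. In these tables as used here, the decimal mark of every value of 1 or more was lost, which affected 51.1% of the RPKM values. Values below 1 had kept it. Whether the marks were lost before or after deposit was not tested. An RPKM value times the library size is a number of reads over a gene length, and so a ratio of whole numbers. The size of each library was estimated from genes with 1 read, and each mark was placed where the value gave whole reads with 1 gene length over all libraries. Where several places gave whole reads, the place nearest to the gene's other values in that tissue was taken. A restored value therefore leans toward the other libraries of its tissue, whatever their genotype. This gave values for 27178 genes, all within 0.001 of whole reads, and 1 gene was left out. Some marks stayed unsure, in 243 genes in striatum and 331 in hippocampus, and those genes were left out of that tissue's limma and list tests. Ikzf4, with 1 such mark in hippocampus, was kept in the exact permutation tests of the Ikaros family. The rule for an unsure mark was set after the data were seen. Its last part, on tissues in which nearly all reads of a gene were multiples of 5, was added after such a gene had appeared as the only call under an alternative. An alternative kept these genes in. The method was tested on simulated values of 12430 genes, in which 99.879% of the lost marks were restored to the true value, and 99.98% in genes with no unsure mark. In 99.75% of those genes all libraries lay on 1 common scale.

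The recovered reads came to between 17638848 and 37489639 per library. Counting noise weighs most, relative to the value, in values that rest on few reads. Recovered reads were used to describe depth and library size, to compare pairs of libraries, for the simulations of the fit and for added alternatives, but not for the main tests. The test planned for read counts was not used, because the deposited values were RPKM, and the branch of the plan written for RPKM took its place. Symbols and positions came from RefSeq and GENCODE annotation of GRCm38, the assembly also called mm10, matched by Entrez identifier, and 25293 genes had a symbol. Reads of overlapping or near-identical genes could not be separated. The hemoglobin genes are such a family, and their values are uncertain for that reason.

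In each tissue, limma 3.58.1 (trend and robust options) in R 4.3.3 compared log2(RPKM + 1) between the libraries labelled knockout and wild type, with no covariate. Genes with an RPKM of at least 0.5 in at least 5 libraries of the tissue were tested, a filter chosen once the unit was known. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Fold changes, other than those of voom and of the authors, are differences of means of log2(RPKM + 1), labelled knockout minus labelled wild type unless labels are said to be exchanged, and understate changes of low genes. Those of voom are on the scale of log2 reads per total and are not comparable in size. The interaction of genotype and tissue was tested over all 20 libraries. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these libraries. Of 40 pairs of libraries within a group, none agreed within counting noise, with a smallest chi-square of 14 per degree of freedom, and none were merged.

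Before the data were examined, 27 gene lists, the comparisons and a set of other settings were fixed. Lists with at least 3 measured members were tested, 25 in striatum and 24 in hippocampus, with camera at the preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. All are part of limma and were adjusted over the lists of a tissue. Genes named by a rule fixed beforehand were the 5 Ikaros family genes, 10 rising and 10 falling called genes per tissue, at most 4 members of each list with the smallest p, and 10 genes of the interaction. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were taken and said not to pass. Predicted genes were passed over, 1 rising gene in striatum and 2 in hippocampus. Further genes are named from the region around Ikzf2, the alternatives, the authors' comparison and the other observations, some of them picked after their values were seen. Single genes were also compared with two-sided exact permutation tests over all splits of the libraries. Enrichment near Ikzf2 and overlap between tissues were tested with two-sided Fisher's exact tests.

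The fit was tested on simulated data with 200 changed genes. In the striatal simulation of 14795 genes it recovered 86.6%, 92.5% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 11 calls among unchanged genes. In the hippocampal simulation of 14820 genes it recovered 68.7%, 94% and 100%, with 2 such calls. All recovered genes had the right direction. These simulations drew noise for each gene separately, and so leave out structure shared by genes within real libraries. They also changed 200 genes at once, which makes the Benjamini-Hochberg cutoff easier to pass than when few genes change. The recovered shares therefore overstate what the real fits could call if few genes changed. Striatal Ikzf2, at 35.1% of its labelled wild-type level, had a limma adjusted p of 0.0862 and was not called. Having 0 calls does not exclude changes of these sizes. The settings fixed beforehand covered the pseudocount, filter, threshold, samples in the fit, each replicate left out, Xist as a covariate, the library codes and the replicate number as a block. Alternatives added after the data were seen were limma voom with quality weights on recovered reads, other scalings, unadjusted p, a level of the cortical list as a covariate and fits without doubtful libraries, and 2 gene lists were written after the data were seen. Restoration and figures used Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9. The results of 2 further tests of 1 pattern, chosen after the data were seen, are not reported here.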

Results

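Gene expression was measured in striatum and hippocampus of mice labelled wild type or Helios knockout, to ask how the transcriptome of each tissue differs without Helios. Each tissue had 5 libraries per genotype, and 17638848 to 37489639 reads per library could be recovered from the deposited RPKM values. Each library also carried a code of 2 numbers. Codes beginning with 6 were all labelled wild type and those beginning with 8 all labelled knockout, in both tissues. Between these codes, genotype cannot be told apart from whatever else the first number records. Code 7_1 was labelled wild type replicate 6 in hippocampus and knockout replicate 6 in striatum, and code 7_6 was labelled knockout replicate 5 in hippocampus and wild type replicate 5 in striatum.

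Mean levels of marker lists were compared between tissues without a test. Markers of direct-pathway spiny projection neurons, the output neurons of striatum, averaged 3.93 (log2 of RPKM + 1) in striatal libraries labelled wild type and 4.01 in those labelled knockout, against 1.44 and 1.37 in hippocampus. Indirect-pathway markers averaged 4.29 and 4.37 in striatum, against 1.7 and 1.62 in hippocampus. Dentate granule cell markers averaged 1.86 and 1.81 in hippocampus, against 1.38 and 1.47 in striatum, with overlap between libraries (1.45 to 2.05 against 1.28 to 1.65). CA1 markers averaged 2.38 and 2.46 in hippocampus, against 2.49 and 2.54 in striatum, and CA2 and CA3 markers 2.43 and 2.49, against 2.37 and 2.51.

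Ikzf2, the targeted gene (Entrez 22779, chromosome 1, 69531207 to 69687351, GRCm38), was lower in striatal libraries labelled knockout, at 0.93 ± 0.158 RPKM (SD, n = 5) against 2.64 ± 0.623 (SD, n = 5), or 35.1% of the level in those labelled wild type. All 5 libraries labelled knockout (0.76 to 1.11) lay below all 5 labelled wild type (2.09 to 3.66; exact permutation p = 0.00794, the smallest that 252 splits allow, and 0.0397 adjusted over 10 tests of the family). In hippocampus the groups overlapped, at 0.747 ± 0.412 RPKM (SD, n = 5) against 1.33 ± 0.333 (SD, n = 5; exact permutation p = 0.0556, 0.185 adjusted). There the library labelled wild type replicate 6, code 7_1, had 0.782 RPKM, below the 1.32 to 1.61 of the other 4 labelled wild type. The library labelled knockout replicate 5, code 7_6, had 1.43 RPKM, above the 0.353 to 0.785 of the other 4 labelled knockout. Ikzf2 thus went against both hippocampal labels of the codes whose genotype differs between tissues, and every hippocampal direction below is drawn from labels that include these 2 libraries. Without both codes Ikzf2 was at 39.4% of the level labelled wild type in hippocampus (0.576 ± 0.178 against 1.46 ± 0.155, n = 4 each; exact permutation p = 0.0286) and at 32.5% in striatum. Reads over Ikzf2 remained in every library labelled knockout, and which part of the gene was targeted is not given in the sources used here.

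**Figure D1:**
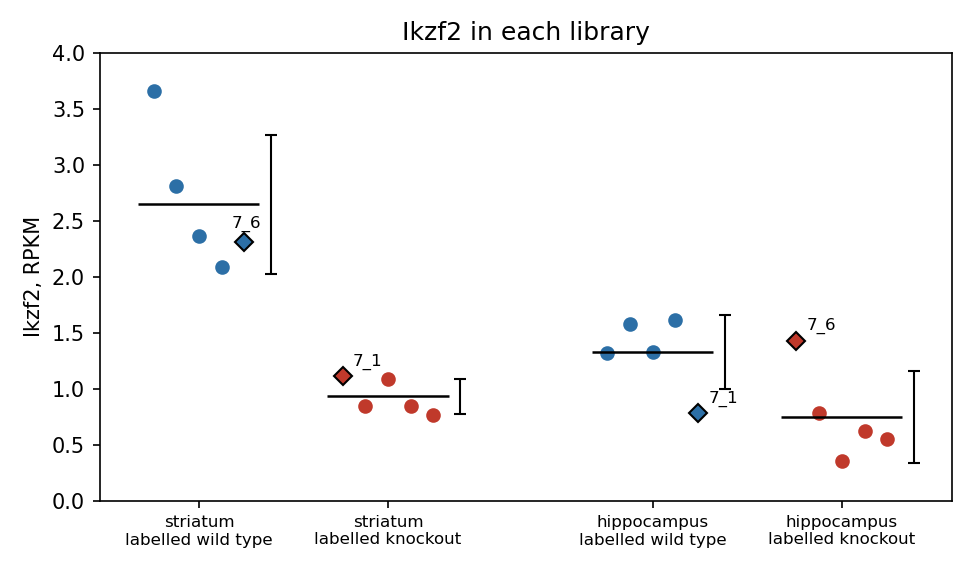
Ikzf2 in RPKM (vertical axis) in each of the 20 libraries, by tissue and labelled genotype; horizontal lines are group means, bars are ± 1 SD (n = 5), and diamonds mark codes 7_1 and 7_6. In striatum both diamonds lie with their labelled group, and in hippocampus 7_1 (0.782) and 7_6 (1.43) lie among the values of the other group.

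Of the other Ikaros family genes in striatum, Ikzf1 was at 14.8 ± 1.7 RPKM in libraries labelled knockout and 18.2 ± 6.7 in those labelled wild type, Ikzf4 at 8.81 ± 1.21 and 9.23 ± 1.63, and Ikzf5 at 9.89 ± 0.895 and 10.1 ± 0.627 (SD, n = 5 each). None of these differed by more than the spread between replicates (exact permutation p = 0.389, 0.714 and 0.683). In hippocampus Ikzf1 was at 0.465 ± 0.122 and 0.456 ± 0.274 RPKM, and Ikzf4 at 5.62 ± 2.05 and 6.4 ± 0.261. That lower Ikzf4 mean includes knockout replicate 8, as labelled, at 2.1 RPKM, a value with an unsure decimal mark, against 5.64 to 7.22 in the other 4. Ikzf5 was at 8.91 ± 2.59 and 10.8 ± 0.226 RPKM there, with all 5 libraries labelled knockout below all 5 labelled wild type (n = 5 each; exact permutation p = 0.00794, 0.0397 adjusted over the family). The margin was narrow, at most 10.4 against at least 10.5 RPKM. Code 7_6, labelled knockout, was at 9.31 and code 7_1, labelled wild type, at 10.7, so the groups would overlap with these 2 labels exchanged. The library labelled knockout replicate 8 stood at 4.34 RPKM. Without it the mean was 10 ± 0.505 (n = 4) and the difference moved from -0.31 to -0.1 on the log2 scale (exact permutation p = 0.00794), while limma over all genes did not call Ikzf5. Ikzf3 was at most 0.0242 RPKM in any library and was listed at 0 in all 5 hippocampal libraries labelled wild type.

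In striatum, ependymal and blood genes had the smallest camera adjusted p at the preset correlation, and no single gene was called. Camera with an estimated correlation called 0 lists, and so did fry. All 5 measured ependymal cell markers were higher in libraries labelled knockout, among them Foxj1, a transcription factor of motile cilia, at 13 ± 2.69 against 8.52 ± 1.03 RPKM, and Dynlrb2, a dynein light chain, at 3.02 ± 0.546 against 1.99 ± 0.837 (SD, n = 5 each). Adjusted over the list alone, 5 of 5 passed (limma; camera adjusted p = 1.19e-06, and adjusted p = 0.134 with an estimated correlation). All 3 measured blood genes were lower, with Hba-a2 at 194 ± 45.8 against 408 ± 128 RPKM and Hbb-bs at 43.9 ± 8.01 against 78.3 ± 17.3, and 3 of 3 passed adjusted over the list alone (camera adjusted p = 1.04e-06, and adjusted p = 0.134 with an estimated correlation). Blood genes mark blood left in the tissue. Both lists kept their camera call when any 1 library was left out, and none of their genes passed over all genes tested.

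Neuronal and glial lists moved less. Shared spiny projection neuron markers were higher in 15 of 16 members (camera adjusted p = 0.00792, and adjusted p = 0.642 with an estimated correlation), with Ppp1r1b, which encodes DARPP-32, at 66 ± 11.6 against 53.1 ± 10.7 RPKM. Synaptic receptor and plasticity genes were higher in 11 of 13 members (0.00746, and adjusted p = 0.578 with an estimated correlation), with the glutamate receptor gene Grm5 at 54.3 ± 8.82 against 41.5 ± 9.08. Oligodendrocyte precursor markers were higher in 6 of 6 (0.0013, and adjusted p = 0.373 with an estimated correlation), with Olig1 at 40.8 ± 3.59 against 31.4 ± 7.76. CA2 and CA3 markers were higher in 5 of 6 (0.00948, and adjusted p = 0.134 with an estimated correlation). In all 4 of these lists no member passed over all genes, and adjusted over the list alone only Bok passed, in the CA2 and CA3 list. Bok lies on chromosome 1 (93685575 to 93695770), within 40 Mb of Ikzf2, and is among the genes examined below for flanking DNA. The levels of CA2 and CA3 markers were alike in both tissues, so this list does not separate striatum from hippocampus here.

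Immature neuron and neurogenesis genes were lower in 9 of 11 members in striatum (camera adjusted p = 0.00792, and adjusted p = 0.223 with an estimated correlation), with the proneural gene Neurog2 at 3.08 ± 1.33 against 5.76 ± 2.35 RPKM. Cell cycle genes were lower in 16 of 17 (0.0203, and adjusted p = 0.642 with an estimated correlation), with Cdk2 at 5.25 ± 0.968 against 6.72 ± 2.39. Meningeal fibroblast markers were lower in 5 of 5 (0.0223, and adjusted p = 0.639 with an estimated correlation), with Ptgds at 1.6 ± 0.548 against 9.1 ± 11.2. The Ikaros family was lower in 4 of 4 (0.00575, and adjusted p = 0.223 with an estimated correlation), and adjusted over the list alone only Ikzf2 passed. This list holds Ikzf2, the targeted gene (-0.91 on the log2 scale), so a lower list was built into the design. Ikzf1 was at -0.23, Ikzf4 at -0.06 and Ikzf5 at -0.03, so the call does not show a decrease across the family. Wild type replicate 4, as labelled, stood above its group in meningeal (4.11 against 1.43 to 2.17), vascular, cell cycle and immature neuron markers. Without it the adjusted p was 0.602 for meningeal, 0.845 for cell cycle, 0.463 for shared spiny projection neuron, and 0.0667 for both the synaptic and the CA2 and CA3 lists. Without knockout replicate 6, as labelled, it was 0.515 for shared spiny projection neuron, 0.0946 for synaptic, 0.306 for cell cycle and 0.0805 for meningeal markers. The cell cycle call was also lost without knockout replicate 7 (0.116), and the meningeal call without wild type replicate 2 (0.0514), knockout replicate 8 (0.0564) or knockout replicate 10 (0.105), all as labelled. The other 15 of 25 lists did not pass, though within the astrocyte list Aqp4, the astrocyte water channel, was at 6.79 ± 1.45 against 4.25 ± 0.937 and passed adjusted over the list alone.

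Of 14795 genes tested in striatum, limma called 0, with 601 at an unadjusted p below 0.05 (303 higher, 298 lower), and limma voom on the recovered reads called 2, Ikzf2 and Lancl1. The smallest adjusted p was 0.0862, for Ikzf2, at -0.91 ± 0.11 (SE) on the log2 scale. The next lower genes were Lancl1, encoding a glutathione-binding protein (14.7 ± 0.504 against 18.5 ± 1.08 RPKM, lower in 5 of 5 libraries than in any labelled wild type; limma adjusted p = 0.577), Maff, D2hgdh, a hydroxyglutarate dehydrogenase (2.14 ± 0.642 against 4.2 ± 0.735), and Kdm3a, a histone demethylase (15 ± 0.831 against 20.1 ± 2.33). The higher genes with the smallest p were Sgpp2, a sphingosine phosphate phosphatase (1.18 ± 0.223 against 0.625 ± 0.0711), Rnf167 (27.4 ± 2.88 against 19.3 ± 3.17), Drc3 and Rsph1, both encoding parts of motile cilia (2.48 ± 0.33 against 1.7 ± 0.161, and 1.98 ± 0.488 against 1.1 ± 0.175), and Bok, a BCL2 family gene (47.1 ± 7.02 against 34.1 ± 3.41). None of the 10 passed.

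In hippocampus, as labelled, ependymal genes and RNA quality and mitochondrial genes were higher as groups, and neurogenesis genes lower. Again no gene was called. No camera call of a hippocampal list remained when the genotypes of the libraries whose labels Ikzf2 went against were exchanged, as given below. Whether RNA quality itself differed between the groups was not tested. Without knockout replicate 8, as labelled, which differed by gene length, the RNA quality and mitochondrial list kept its call (camera adjusted p = 0.00159). All 4 measured ependymal markers were higher, with Dynlrb2 at 4.79 ± 1.54 against 2.34 ± 0.457 RPKM and Foxj1 at 19 ± 4 against 13.1 ± 1.69 (SD, n = 5 each), and 2 of 4 passed adjusted over the list alone (limma; camera adjusted p = 0.00192, and adjusted p = 0.501 with an estimated correlation). The list of RNA quality and mitochondrial genes was higher in 10 of 12 members (0.00577, and adjusted p = 0.501 with an estimated correlation), with mt-Nd4 at 3020 ± 227 against 2600 ± 270 and the noncoding RNA Meg3 at 105 ± 19 against 78.9 ± 11.3. Immature neuron and neurogenesis genes were lower in 11 of 13 (0.00853, and adjusted p = 0.527 with an estimated correlation), with Neurog2 at 26.2 ± 3.47 against 33.2 ± 4.37 and Eomes, a marker of neuronal progenitors, at 29.6 ± 5.63 against 37.2 ± 4.61. Cell cycle genes were lower in 13 of 16 (0.0206, and adjusted p = 0.534 with an estimated correlation), with Mcm2 at 9.33 ± 1.4 against 11.1 ± 0.931.

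Markers of tissue lining the brain and its ventricles were also higher in hippocampal libraries labelled knockout. Meningeal fibroblast markers were higher in 8 of 8 members (camera adjusted p = 0.00853, and adjusted p = 0.534 with an estimated correlation), with Slc22a6 at 3.2 ± 1.74 against 1.66 ± 0.583 RPKM. Choroid plexus markers were higher in 7 of 8 (0.0278, and adjusted p = 0.534 with an estimated correlation). Kcnj13, on chromosome 1 within 20 Mb of Ikzf2, was at 1.04 ± 0.463 against 0.45 ± 0.138. It was the only member to pass adjusted over the list alone. The library labelled knockout replicate 5, code 7_6, had a mean list level (log2 of RPKM + 1) of 1.67. Others labelled knockout had 0.51 to 1, and those labelled wild type 0.5 to 0.94. The direction of this list reversed with the genotypes of codes 7_1 and 7_6 exchanged. The choroid plexus call was lost without wild type replicate 6 (adjusted p = 0.106), knockout replicate 5 (0.504) or knockout replicate 9 (0.147), the cell cycle call without wild type replicate 1 (0.082) or knockout replicate 5 (0.162), and the meningeal call without wild type replicate 1 (0.0814), all as labelled. With the genotypes of codes 7_1 and 7_6 exchanged, camera called 0 of 24 lists in hippocampus, and without both codes it called 2. Immediate early genes, which respond to neuronal activity, did not pass (0.115), with Fos at 0.681 ± 0.151 against 1.02 ± 0.12, nor did the other lists.

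**Figure D2:**
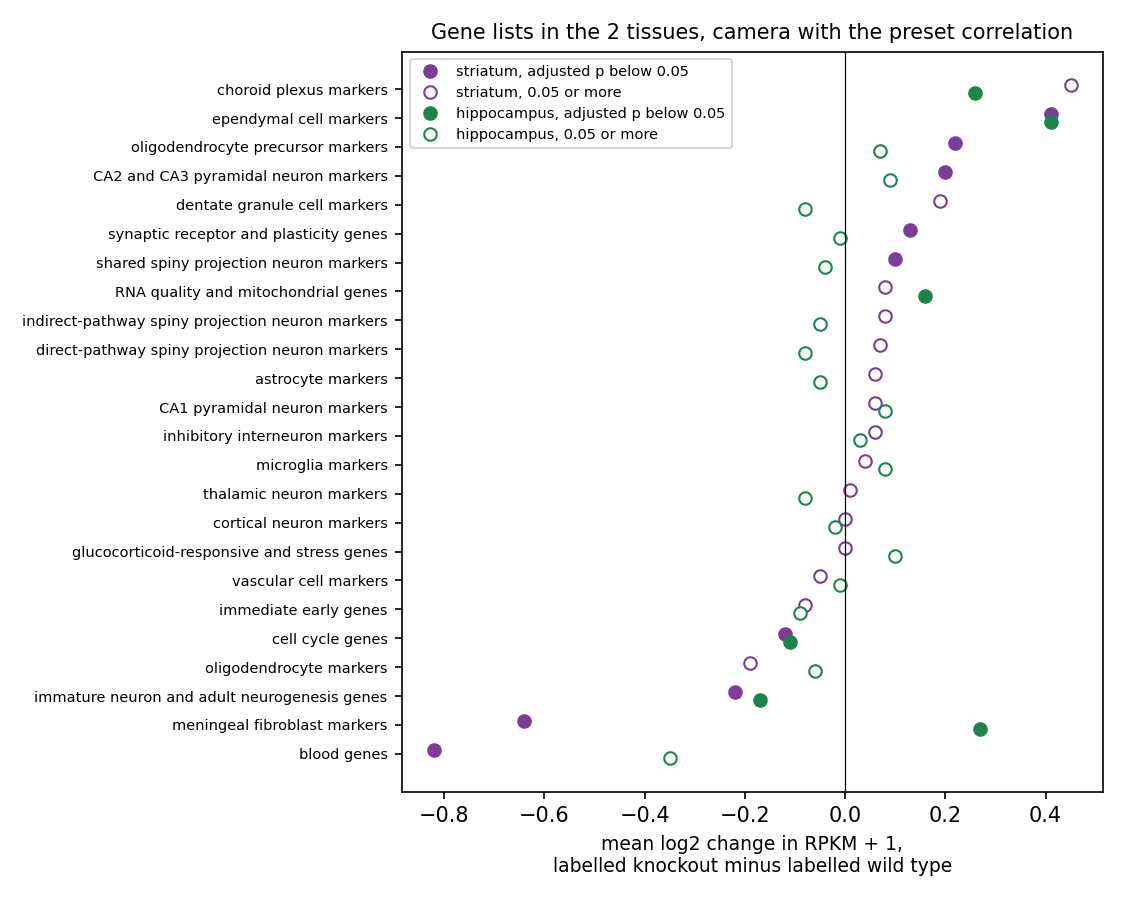
Mean log2 change in RPKM + 1 (horizontal axis, labelled knockout minus labelled wild type) of the 24 gene lists tested in both tissues; filled points had a camera adjusted p below 0.05 at the preset correlation, and none did with an estimated correlation. Ependymal markers lie at 0.41 in both tissues, and meningeal fibroblast markers at -0.64 in striatum and 0.27 in hippocampus; the striatal call was lost without wild type replicate 4, as labelled (adjusted p = 0.602).

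Of 14820 genes tested in hippocampus, limma called 0, with 659 at an unadjusted p below 0.05 (382 higher, 277 lower), and limma voom on the recovered reads called 0. The smallest adjusted p was 0.727. The higher genes with the smallest p were Ogn, a proteoglycan of connective tissue (7.85 ± 1.62 against 3.46 ± 1.33 RPKM), Klf2, a transcription factor of vascular cells (5.26 ± 0.908 against 3.16 ± 0.807), Aifm3 (2.31 ± 0.557 against 1.22 ± 0.217), Spag8 and Dynlrb2. The lower ones were Smad7, an inhibitor of TGF-beta signalling (2.19 ± 0.196 against 3.09 ± 0.207), Stc2 (1.38 ± 0.268 against 2.32 ± 0.349), Mxi1, an antagonist of MYC (11.9 ± 0.837 against 14.5 ± 0.664), Rell1 and Narf. None of the 10 passed. The library labelled knockout replicate 8 differed from the rest by gene length, with a median log2 difference from the other libraries of 0.73 in genes shorter than 1 kb and -0.64 in genes longer than 5 kb.

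The interaction asked whether the difference between labelled genotypes depended on the tissue. The retinoic acid binding protein gene Crabp2 had the smallest p, with a log2 change of -0.52 in striatum and 0.97 in hippocampus (difference -1.48 ± 0.34, SE). The sulfate transporter gene Slc13a4 followed at a difference of -1.27 ± 0.29, and the other 8 genes with the smallest p were Phkg2 (-0.29), Pcdhb4 (0.47), Kcnj13 (-0.58), Mir665 (-1.15), Crtc2 (-0.37), Adamtsl4 (-0.35), Tpcn2 (-0.39) and Mir3473d (-0.97). None passed, with a limma adjusted p of 0.813 for each. Over 15253 genes limma called 0, with 520 at an unadjusted p below 0.05, and limma voom called 0. Ikzf2 differed by -0.48 ± 0.2 (SE; limma adjusted p = 0.813), with the hippocampal labels of codes 7_1 and 7_6 as given.

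No gene was called in both tissues by limma, since 0 were called in either. At an unadjusted p below 0.05, 572 striatal and 595 hippocampal genes among 14108 tested in both shared 49 genes, 18 higher in both, 23 lower in both and 8 in opposite directions, where independent lists would give 6.6, 5.45 and 12.1 (odds ratio 2.23, two-sided Fisher's exact p = 2.1e-06). Lower in both were Ikzf2, Lancl1, Kdm3a and Neurog2, and higher in both were Rnf167, Foxj1 and Dynlrb2. Without both codes of disputed genotype, 60 genes had the same direction and 6 the opposite. The tissues may come from the same animals, so the lists need not be independent even with no effect of genotype, and genes are not independent replicates.

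Genes around Ikzf2 were examined because a knockout allele can carry flanking DNA of another strain. No gene was called by limma within 20 Mb of Ikzf2 in either tissue. At an unadjusted p below 0.05, 17 of 202 striatal genes within 20 Mb passed (8.42%, 10 higher and 7 lower), against 4.03% of 14108 genes elsewhere (odds ratio 2.19, 95% interval 1.24 to 3.63, two-sided Fisher's exact p = 0.00593). They included Lancl1 (chromosome 1, 67000517 to 67038891) and Sgpp2 (78309549 to 78420289). In hippocampus 11 of 202 passed (5.45%, against 4.42% elsewhere, Fisher's exact p = 0.488). Without codes 7_1 and 7_6 the striatal count was 13 (Fisher's exact p = 0.238) and the hippocampal count 12 (Fisher's exact p = 0.0461).

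**Figure D3:**
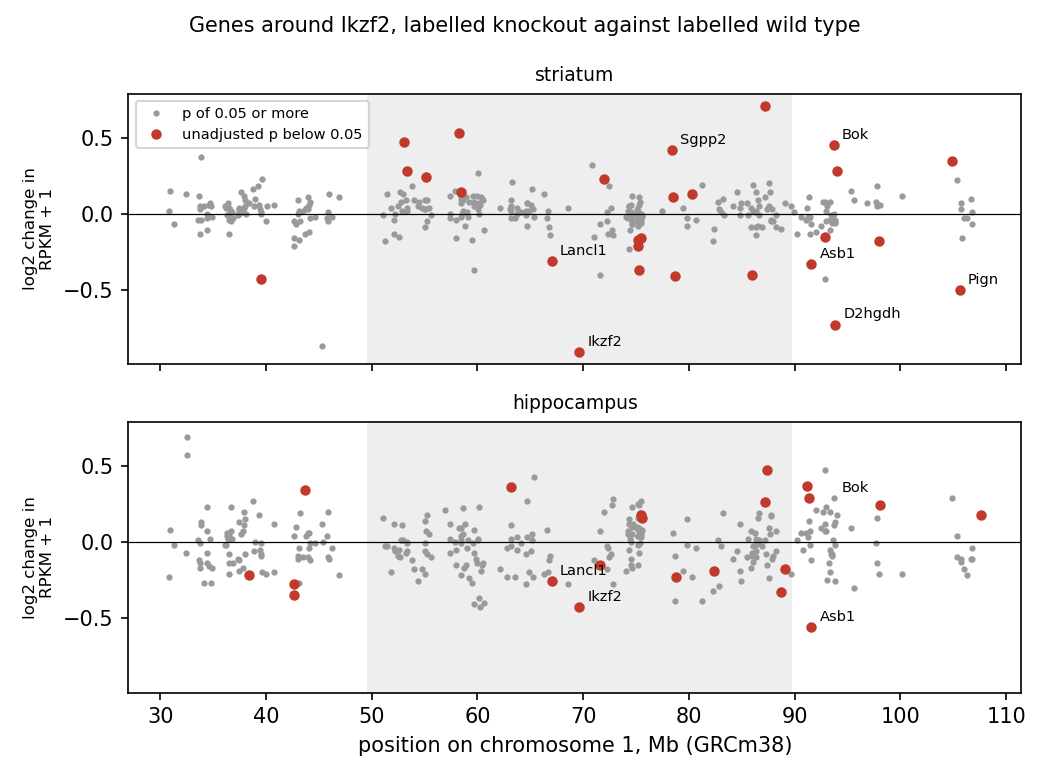
Log2 change in RPKM + 1 (vertical axis, labelled knockout minus labelled wild type) of genes on chromosome 1 within 40 Mb of Ikzf2 by position in Mb (GRCm38), in striatum and hippocampus; red points had an unadjusted limma p below 0.05, none passed after adjustment, and the grey band spans 20 Mb to either side. In striatum 17 genes in the band besides Ikzf2 are red, and in hippocampus 11.

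The authors' deposited table for striatum listed 44 entries with an adjusted p below 0.05, of which 28 were spike-in RNAs, all higher, and 16 were transcripts, 11 higher and 5 lower. In the authors' deposited table Ikzf2 was at -1.15 ± 0.12 (SE) on the log2 scale, Wdfy1 at 1.03, Lancl1 at -0.82, D2hgdh at -0.63, Sgpp2 at 0.53, Foxj1 at 0.45 and Pign at -0.45. The authors' deposited table for hippocampus listed 34, of which 27 were spike-in RNAs, 24 higher and 3 lower, and 7 were transcripts: Ikzf2 at -1.07 ± 0.14 (SE), Pth2r at 1.08, Wdfy1 at 0.85, Vsnl1 at 0.35, Lancl1 at -0.62, Kcne4 at -0.71 and D2hgdh at -0.64. Of these 7 in the authors' deposited table, all but Vsnl1 lie on chromosome 1, between 65280282 and 93853857. Of the authors' 16 striatal transcripts, Ikzf2, Wdfy1, Lancl1, D2hgdh, Sgpp2, Bok and Pign lie on chromosome 1, between 67000517 and 105663741, and the others on other chromosomes. Wdfy1 had an unsure decimal mark and was left out of the striatal fit.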

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

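The tests chosen only after the result was seen were those of the genes near Ikzf2 at an unadjusted p, of the position of codes 7_1 and 7_6 among those genes, of the authors' comparison in each tissue, of splits at an unadjusted p and of lists in the interaction, with and without 1 library, while the counts of called genes over other splits, the test of called genes near Ikzf2 and the test of codes 7_1 and 7_6 over called genes were planned.

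Among 166 groups of 5 libraries, 19 held a library far from the other 4, where chance gives about 1 in 20. The library labelled hippocampal knockout replicate 8 stood apart for Ikzf5 (4.34 RPKM, others 9.31 to 10.4), Klf2 (6.83, others 4.53 to 5.08), the Ikaros family list (0.84, mean log2 level), cortical neuron markers (2.74), glucocorticoid-responsive and stress genes (3.42) and synaptic genes (4.03). The library labelled striatal wild type replicate 4 stood apart for meningeal (4.11), vascular (3.1), thalamic (2.05), cell cycle (4.03) and immature neuron markers (5.71). Its library size as implied by RPKM was 1.02 times its recovered reads, others 0.977 to 0.986. That ratio was 0.746 in hippocampal knockout replicate 7, as labelled, and at least 1 in the rest of its group. Hippocampal wild type replicate 6, as labelled, stood apart for Ikzf1 (0.93 RPKM, others 0.273 to 0.446) and direct-pathway markers (1.66). Striatal knockout replicate 6, as labelled, stood apart for D2hgdh (3.28 RPKM, others 1.78 to 1.97) and shared spiny projection neuron markers (5.63), and replicate 9 for meningeal (1.72) and thalamic markers (2.21).

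Meningeal fibroblast markers passed in the interaction (camera adjusted p = 0.00023, and adjusted p = 0.985 with an estimated correlation), with the library labelled striatal wild type replicate 4 at 4.11 against 1.43 to 2.17 in its group; without it the striatal call was lost (adjusted p = 0.602), and the interaction shrank from -0.87 to -0.38 on the log2 scale and still passed (camera adjusted p = 0.00925 at the preset correlation). In the authors' deposited tables, 27 spike-in RNAs in hippocampus (24 higher, 3 lower) and 28 in striatum (28 higher, 0 lower) had an adjusted p below 0.05.

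Counts of called genes over other splits decide nothing, since limma called 0 genes in the real split and all 100 drawn splits must reach that in striatum (highest other 6), in hippocampus (highest other 2) and, as regroupings within tissues, for the interaction (highest other 1). At an unadjusted p below 0.05, 40 of 100 striatal splits, the real one included, gave at least the real 601 genes, 4 of 100 in hippocampus the real 659 as labelled (highest other 769), and 46 of 100 regroupings the real 520 of the interaction (highest other 2214). A striatal split reached 2862, which points to a structure of those libraries other than labelled genotype.

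Ikzf2 in hippocampus went against the labels of codes 7_1 (0.782 RPKM, labelled wild type) and 7_6 (1.43, labelled knockout), and exchanged labels are a candidate explanation. Of all 126 splits of the hippocampal libraries, the exchanged one had the highest Pearson correlation across genes with the authors' fold changes (r = 0.734, as labelled 0.633, highest other 0.656; genes are not independent replicates), so the authors' comparison may have used genotypes other than the titles give. In striatum the split as labelled had the highest (r = 0.828, exchanged 0.457), and Ikzf2 there went with both labels (1.11 RPKM in 7_1, labelled knockout, and 2.31 in 7_6, labelled wild type). The planned test had no called genes to run on (0). Over 13 genes near Ikzf2, 11 put hippocampal 7_1 nearer the knockout side than 7_6, but a pair of hippocampal libraries sharing a first number reached 12. The striatal pair of 7_1 and 7_6, whose labels Ikzf2 went with, reached only 10. A pair with rightly labelled genotypes could therefore miss this bar, so the test cannot decide and leaves exchanged labels open. An exchange of tubes also stays open, and no biological explanation was tested.

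Genes near Ikzf2 passed an unadjusted p more often than others in striatum (Fisher's exact p = 0.00593), which would be expected if DNA of another strain surrounded the knockout allele, while Fisher's exact p was 0.488 in hippocampus as labelled and, without codes 7_1 and 7_6, 0.238 in striatum and 0.0461 in hippocampus. The planned form of this test was void, with 0 called genes. Loss of Helios alone stays open: in 5 of 5 genes within 40 Mb picked for a p below 0.001 between the striatal libraries of codes 6 and 8, striatal 7_1, with low Ikzf2, lay on the wild-type side of all code 8 libraries, but a library left out of such a choice is expected nearer the middle, and Ikzf2 itself lay so (1.11 against at most 1.09 RPKM). Striatal 7_1 lay within the code 6 range for D2hgdh (3.28 in 3 to 4.91) and Pign (4.19 in 3.82 to 5.11). For Lancl1, Asb1, Bok and Ikzf2 it lay between the ranges of codes 6 and 8. Hippocampal 7_1, labelled wild type but with low Ikzf2, lay on the wild-type side of all code 8 libraries for Asb1 (13 against at most 9.92). It also did for D2hgdh (5.11 against at most 2.53) and Pign (5.06 against at most 3.7), both with an unsure decimal mark in 1 library each. These 2 values lay within the code 6 range (4.21 to 6.38 and 4.96 to 6.27). For Bok hippocampal 7_1 did so only narrowly (28.5 against at least 28.9) and lay above all code 6 libraries (22.8 to 26.4). For Lancl1 it did not. Flanking DNA and loss of Helios still cannot be told apart in these genes, because both 7_1 libraries may come from 1 animal and the hippocampal one is labelled wild type.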

How the results depend on the processing

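The tests chosen only after the data were seen were voom, the scalings, unadjusted p, the cortical covariate, unsure marks kept in, and fits without doubtful libraries; the rest were planned.

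The DESeq2, voom, size factor and library-size alternatives planned for counts, and RPKM as an alternative to counts, were not run, because the deposited unit was RPKM. Depth limits genes with few reads; Ikzf2 had 59 to 935 per library. Among the results that answer a comparison, 200 values stayed on their side of the threshold, 25 counts moved by over 1.5 times, 3 values crossed the threshold and 1 reversed. Of the named genes and lists, 534 values stayed, 44 lost and 1 gained a call and 3 reversed. Tests that stayed uncalled are among those that stayed, so these tallies do not measure support for any difference.

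In striatum, 1 fit of all 20 libraries called 1 gene, Ikzf2 (-0.91, limma adjusted p = 0.046), and voom called 2 (Ikzf2 -1.58, adjusted p = 0.00622). Under other scalings Ikzf2 had an adjusted p of 0.0668 (rescaled) and 0.205 (quantile). List calls went from 10 to 0 with an estimated correlation and 6 with labels of codes 7_1 and 7_6 exchanged, where shared spiny projection neuron markers reversed (-0.08). Bok reversed with the first number of the code as a term (-0.08). In hippocampus, exchanged labels called 2 genes (Pth2r, Scarna9), and with voom 8 (Ikzf2 -1.11, adjusted p = 0.00044). Voom with exchanged labels also called Lancl1, Pth2r, Vsnl1, Kcne4, Kdm3a, Nbl1 and Vegfa. Of the 8, Ikzf2, Lancl1, Pth2r, Vsnl1 and Kcne4 are also among the authors' called hippocampal transcripts, and Kdm3a, Nbl1 and Vegfa are not. List calls went from 6 to 0 with an estimated correlation, 0 with exchanged labels and 2 without both codes. Choroid plexus markers reversed under exchanged labels (-0.33), and Ikzf2 with the first number as a term (0.45), a term that leaves genotype to codes 7_1 and 7_6. Apart from that term, the cause was not tested.

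At an unadjusted p below 0.05 there were 601 genes in striatum, 659 in hippocampus and 520 for the interaction. Genes near Ikzf2 numbered 17, 9 and 26 in striatum within 20, 10 and 40 Mb, 13 without both codes and 12 exchanged. In hippocampus they numbered 11, 6 and 20, then 12 and 15. Genes with the same direction in both tissues numbered 41, 34 exchanged and 60 without both codes.

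Leaving out 1 library at a time, Ikzf2 ranged from -0.96 to -0.81 in striatum, -0.56 to -0.34 in hippocampus and -0.56 to -0.35 for the interaction, and list calls from 7 to 12 and 4 to 9.

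Replicate numbers shared between tissues were not taken to pair the libraries, since 8 and not all of 10 pairs correlated over 0.1 (-0.18 to 0.23) and 2 of 10 correlated best with their own number, but the same animals stay possible. With the replicate block the interaction had 0 calls (limma) and Ikzf2 was at -0.32 (adjusted p = 0.729), and without replicates 5 and 6 at -0.32 (0.798).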

Other observations

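All tests of this part were chosen only after the result was seen.

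Genes known to respond to low oxygen were lower in both tissues at an unadjusted p below 0.05, and they were picked out here after their values were seen. Vegfa, a growth factor for blood vessels, was at -0.41 on the log2 scale in striatum and -0.3 in hippocampus, the glucose transporter gene Slc2a1 at -0.39 and -0.42, Ddit4 at -0.41 and -0.43 and Kdm3a at -0.39 and -0.43. A list of low-oxygen response genes was then written from textbook knowledge, leaving out every gene already seen to move. All 16 measured members were lower in striatum (mean -0.13; camera p = 0.0095 with an estimated correlation, 0.038 adjusted over 4 such tests), with Ankrd37 at -0.22 and Adm at -0.31. Without codes 7_1 and 7_6, 14 of 17 were lower there (mean -0.08 ± 0.06, SE over members; camera p = 0.0369 with an estimated correlation, fry p = 0.0678, neither adjusted). In hippocampus, as labelled, 13 of 17 were lower (mean -0.08; p = 0.188 with an estimated correlation), and 14 of 17 without codes 7_1 and 7_6 (p = 0.0545). The theme of this list was chosen from values of the same libraries, so its striatal p-values are not independent support. That genes of the low-oxygen response may be lower as a group in libraries labelled knockout is a hypothesis. These libraries cannot test it independently, and in hippocampus the list did not pass. The way the tissue was collected was not recorded in the labels used here, and blood genes were also lower in the striatal libraries.

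Further genes of motile cilia were higher in both tissues at an unadjusted p below 0.05, also picked out after their values were seen. Deup1, of the structure that builds centrioles in multiciliated cells, was at 0.49 in striatum and 0.41 in hippocampus on the log2 scale, Ccno at 0.39 and 0.53 and Zmynd10 at 0.44 and 0.48. A list of motile cilia genes, again without any gene already seen to move, was higher in 14 of 15 members in striatum (mean 0.14; camera p = 0.0985 with an estimated correlation) and 12 of 15 in hippocampus (mean 0.09; p = 0.171, the value that decides for both tissues). Rsph9 was taken off this list after a first run, because its value had been seen before the list was written, and with it the list had not passed in either tissue. With the hippocampal genotypes of codes 7_1 and 7_6 exchanged it was higher in 8 of 15 (mean 0). Higher expression of cilia genes as a group was therefore not shown.

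Sex-linked genes followed the library codes across tissues. Codes 6_1, 6_7 and 8_7 had Ddx3y between 11.9 and 15.8 RPKM and Xist of at most 0.236 in both tissues, and the other codes had Ddx3y at 0 and Xist of at least 58.4. Codes 7_1 and 7_6 were alike in these genes, which therefore do not tell them apart.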
